A study of Homo sapiens with 8 samples.

How the data were processed

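Gene expression was measured with 8 one-colour microarrays in THP-1 cells, an established human line derived from acute monocytic leukaemia. The labels number 4 experiments, each with 1 culture in control medium and 1 in medium without the branched-chain amino acids (BCAA) leucine, isoleucine and valine, so each group holds 4 arrays. Per the labels, cells grew in DMEM/F-12 with fetal bovine serum, and experiments 1, 2, 3 and 4 lasted 4, 4, 5 and 3 days. One characteristic of the BCAA-free samples states a longer time without BCAA than their source names and the treatment protocol do, and the times of the source names were used. The cells were purified by flow cytometry, per the series' design text. Total RNA was labelled with Cy3 using an Agilent low-input kit and hybridised to Agilent arrays designed on the human build hg19, per the labels and the file headers.

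The scanner files hold the intensity of each spot, which the authors obtained with Agilent Feature Extraction 11.5.1.1, per the submitters' processing notes and the file headers. The processed intensity in these deposited files is background-subtracted and spatially detrended by that software, per the file headers, and is not scaled between arrays. The authors also deposited a table of log2 values of the same arrays. Set against the scanner values over 18447 probes with a signal above 50, each column of it equalled the log2 processed signal minus the array's 75th percentile, centred on each probe's median over the 8 arrays, with correlations across probes of at least 0.9999. Its scale, centring and direction were thereby settled. The medians of its columns were -0.0467, -0.1158, -0.1677 and -0.0241 for control 1 to 4 and -0.0125, 0.2194, 0.0857 and 0.0546 for BCAA-free 1 to 4.

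Control spots and spots marked as outliers by the scanner software were left out, spots of 1 probe were averaged, and log2 of the processed signal was taken relative to each array's 75th percentile over probes. All levels below are on this scale. Of 58201 probes, 300 were printed on more than 1 spot, and 154 had all their spots marked on at least 1 array. The files name no genes, so each probe's accession was matched to a RefSeq gene table of assembly GRCh38.p14, used for names only because the array was designed on another build. It gave 31104 probes 1 gene symbol (22439 symbols), no probe several, and 27097 probes none. Coordinates were not used here. Each gene was represented by its brightest probe with values on all arrays, which 22382 genes had and 57 had not. A gene was tested if that probe was well above background, as marked by the scanner software, on all 4 arrays of at least 1 group, which left 15759 genes. Other probes of a gene that passed the same filter existed for 187 of the genes that changed, and for 19 of these at least 1 other probe had the opposite sign. Among named genes this held for RIGI alone.

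Brightness differed between arrays. The 75th percentile of the processed signal was 606, 353, 674 and 280 on control 1 to 4 and 244, 194, 454 and 272 on BCAA-free 1 to 4, and no spot was saturated. The share of probes well above background ranged from 51.1% to 66.5%. The number of arrays, 4 per group, limits the precision of every comparison. P-values of the main fit measure the spread among the 4 arrays within each group, which also holds differences shared by both arrays of an experiment. All arrays lay on 1 slide and were scanned together. Control arrays took the upper row of that slide and BCAA-free arrays the lower row, so the slide row and the group cannot be told apart. A fit with the slide or the scan as a block was not possible with a single slide.

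Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without a block), p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene changed if its adjusted p was under 0.05. A second threshold asked in addition for a change of at least 2-fold. A probe below background on every array of a group gives only a bound. Its "at least" fold sets the mean of the brighter group against the mean of, per array, the higher of the probe's own level and the lowest level among probes well above background. Gene lists were fixed before the data were examined, 36 in all, of which 3 were markers of cell types that THP-1 cells are not. A list was tested with camera at a preset correlation between genes of 0.01, and counts of changed members are given over all genes tested and adjusted over the list alone. With the correlation estimated from the residuals, none of the lists was shifted. The gene set test fry was also run. It asks whether the genes of a list move one way on balance, without comparing them with other genes. The dependence of the response on culture time was tested with limma as the slope of the 4 within-experiment log2 ratios on the number of days.

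Named genes followed a rule fixed before the data were examined. They were the 8 largest rises and 8 largest falls among genes past the threshold with 1 sign in all 4 experiments and a probe well above background on all 4 arrays of the higher group, leaving out names that are not gene symbols, antisense names, XIST and Y-linked genes. Added to these were up to 3 changed members of each shifted list in the direction of the list, at most 1 changed member of each other list, and BCAT1, BCAT2, EZH2, EED, SUZ12, ASNS, DDIT3, MYC and CD14 whatever their result. EED was not analysed here. This named 69 genes with values, of which some are not reported here.

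Samples of the same number come from 1 experiment with the same culture time in the labels. Their deviations from the group means correlated across genes at 0.371, 0.177, 0.320 and 0.312 for experiments 1 to 4, all above 0.1, and the numbers were therefore taken to pair the samples. Control 2 correlated more closely with another BCAA-free array (0.230) than with its own partner. The blocked fit, with the experiment as a block, is given beside a result where it changed a call or moved a count by over 1.5 times.

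The fit was tested on simulated data drawn 5 times from the means and the spread of the 15759 genes, with 200 genes changed for the comparison of BCAA-free with control. Without the block it recovered 22.5% of the genes changed by 1 log2 unit and 93.2% of those changed by 2, and 1.77% of its calls were false. With the block these shares were 54.5%, 98.8% and 7.96%. A mitosis list lowered by 1 log2 unit was called in each draw and no other list was. The simulated genes varied independently of each other, whereas real mitosis genes had an estimated correlation of 0.38. The draws therefore cannot show how specific the list test is.

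Alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, the authors' deposited log2 values, no filter on dim probes, a filter on all 8 arrays, the mean of all probes of a gene, limma's trend and robust options, array weights, the block, only the experiments of 4 days, and leaving out each array and each experiment. Because the files hold median rather than mean spot signals, normexp used the median spot and background intensities. Its offset of 50 exceeded the median processed signal of every array (12.4 to 37.9), so it shrinks the changes of dim probes. After scaling to the 75th percentile it also places such probes higher on dimmer arrays. In each experiment the BCAA-free array was the dimmer one. A smaller or reversed fall of a dim probe under normexp is therefore partly built in. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.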

Results

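The series compared THP-1 cells, an established human acute monocytic leukaemia line, grown with or without the branched-chain amino acids (BCAA) leucine, isoleucine and valine. Its design text places it in the study of how acute myeloid leukaemia cells respond when BCAA metabolism is blocked. In each of 4 numbered experiments 1 control and 1 BCAA-free culture were measured on one-colour microarrays, giving 4 arrays per group. Between 51.1% and 66.5% of 58201 probes were well above background on an array. Levels are log2 signals relative to the 75th percentile of the array, and 15759 genes were tested.

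Without BCAA, 260 genes rose and 516 fell. Under percentile scaling the largest rises past the threshold were those of GDAP1L1 (log2 fold change 4.35 ± 0.85, SE, n = 4, adjusted p = 0.023), whose change was only 2.43 under normexp, and DRD5, a dopamine receptor, which was 19.6-fold higher. Next there was S100P, a calcium-binding protein, from a level of 4.77 ± 1.63 (SD, n = 4) in control to 9.0 ± 0.21 (SD, n = 4), or 18.8-fold, at an adjusted p of 0.011. NNMT, which methylates nicotinamide, was 18.2-fold higher, and PRSS8, a membrane-anchored serine protease, 16.7-fold higher (log2 4.07 ± 0.41, SE, n = 4, adjusted p = 0.0033). The folate receptor gene FOLR3 rose, with a probe well above background on only 1 control array, which leaves the size of its change uncertain (log2 3.63, and 1.04 under normexp). NNMT was above background on 3 control arrays (log2 4.19, and 2.22 under normexp). The acute-phase protein genes ORM2 and ORM1 were 11.9-fold and 11.4-fold higher (log2 3.57 and 3.52, and 1.93 and 1.98 in the experiments of 4 days alone, where no gene passed). They are near-identical copies, and their transcripts cannot be separated here. With single arrays left out GDAP1L1 and FOLR3 passed in 4 of 8 cases (adjusted p up to 0.067 and 0.063) and ORM2 and ORM1 in 2 (up to 0.091 and 0.078), while DRD5, S100P, NNMT and PRSS8 passed in all 8.

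The largest fall was that of FADS2, a fatty acid desaturase, from 5.24 ± 1.33 (SD, n = 4) to 0.69 ± 0.38 (SD, n = 4), which is 23.4-fold lower at an adjusted p of 0.0068. PRL, which encodes prolactin, fell and was well above background on only 1 BCAA-free array, so that its size is uncertain too (log2 -4.17, and -0.97 under normexp, where it did not pass). JAML, a junctional adhesion molecule, and GLIPR1 were 15.5-fold and 14.3-fold lower, each above background on 3 BCAA-free arrays (log2 -2.25 and -1.80 under normexp). VIM, the intermediate filament protein vimentin, fell from 4.41 ± 1.64 to 0.75 ± 1.22 (SD, n = 4 each), or 12.7-fold. ANXA2, which encodes annexin A2, fell from 4.63 ± 0.64 to 1.0 ± 0.52 (SD, n = 4 each), or 12.4-fold, at an adjusted p of 0.0033. Probes for its processed pseudogenes moved with it. ANXA2P1 was 12.3-fold lower. ANXA2P3 was below background on all 4 BCAA-free arrays and at least 4.90-fold lower under percentile scaling, but under normexp its log2 change was only -0.68 and did not pass. These sequences cannot be separated from ANXA2 here. With single arrays left out VIM passed in 2 of 8 cases (adjusted p 0.0063 to 0.084) and JAML in 6 (up to 0.056), and the other falls named here in all 8.

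**Figure D1:**
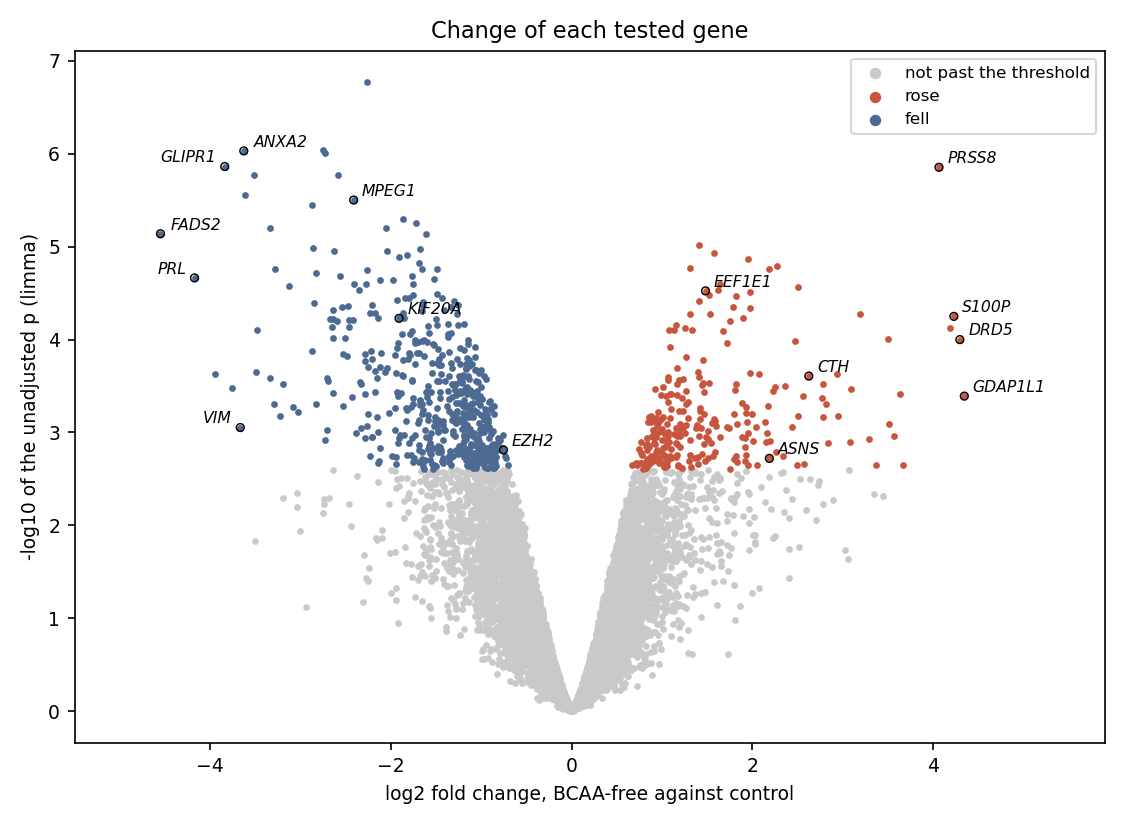
Each point is a tested gene (XIST and Y-linked genes are not drawn), with the log2 fold change of BCAA-free against control on the x axis and -log10 of limma's unadjusted p on the y axis. Genes that rose are red, genes that fell are blue, and the circled and labelled genes run from FADS2 at -4.55 to GDAP1L1 at 4.35.

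In all, 776 genes changed, 636 of them at least 2-fold, and 775 of the 776 had 1 sign in all 4 experiments. At an unadjusted p under 0.05 there were 3616 genes. With the experiment as a block 642 genes rose and 1019 fell, 1661 in total, and 771 of the 776 were called the same way again. At least 2-fold, the blocked fit called 1079. The count changed when single arrays were left out. It was 420, 1229, 247 and 197 without control 1, 2, 3 and 4 and 427, 204, 474 and 307 without BCAA-free 1, 2, 3 and 4. Such fits hold fewer arrays and so have less power, and only the loss of control 2 raised the count. At an unadjusted p under 0.05 in limma they gave 2774 (without control 3) to 4046 genes (without control 2). With the experiments of 4 days alone, 2 arrays per group, it was 0 (1650 genes at an unadjusted p under 0.05), and with no filter on dim probes 229 (228 at least 2-fold). Of the 63 named genes that changed, 21 passed without each of the 8 arrays in turn.

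**Figure D2:**
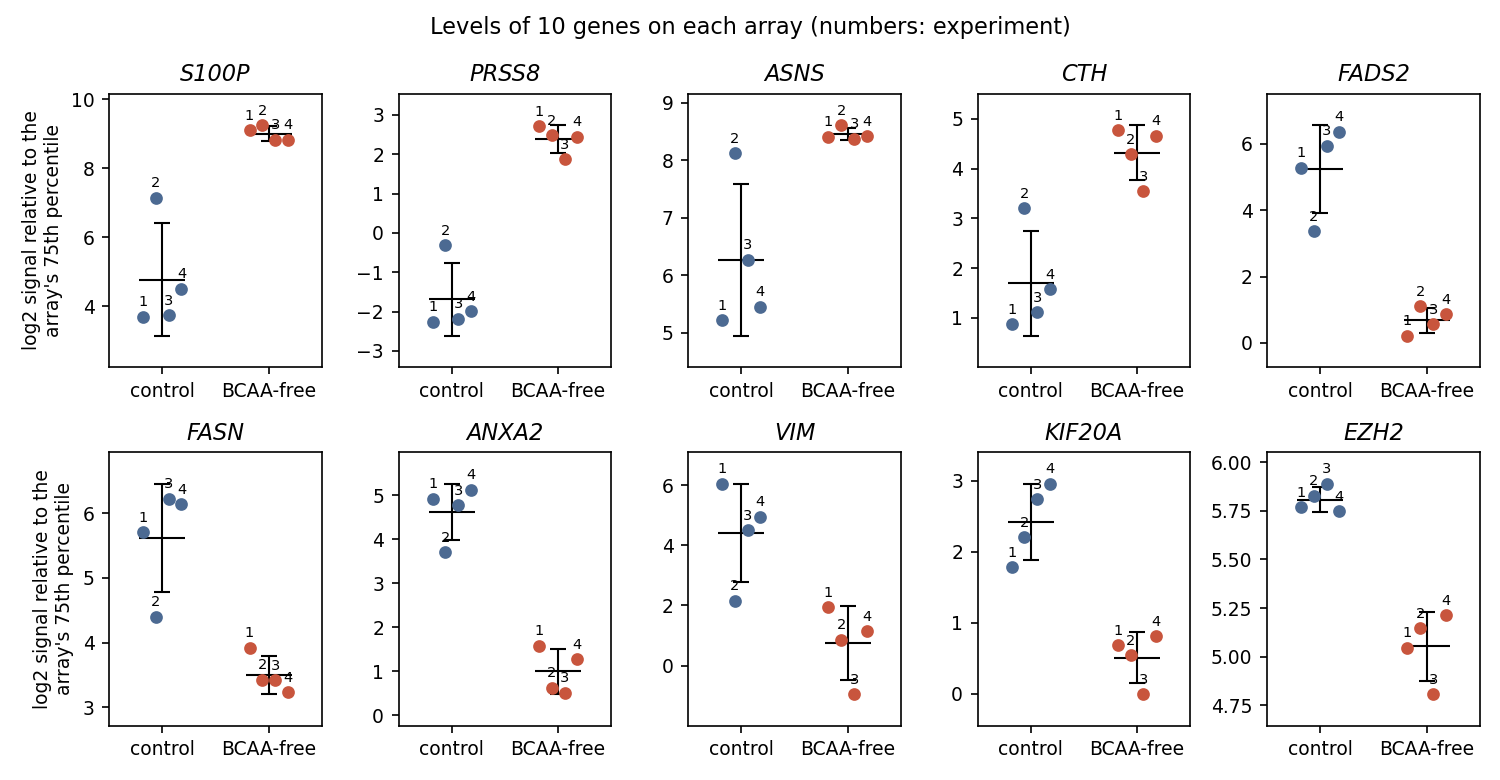
Log2 level of 10 named genes on each array, relative to the array's 75th percentile, with points for arrays numbered by experiment and bars for the group mean ± SD. Control 2 lies above the other 3 controls for S100P, PRSS8, ASNS and CTH and below them for FADS2, FASN, ANXA2 and VIM, while EZH2 spans 5.75 to 5.89 over the 4 controls.

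Genes of the amino acid response, which the transcription factor ATF4 drives when amino acids are short, were higher without BCAA. All 25 tested members had a positive change and the median was 1.52 on the log2 scale. The list was shifted up (camera adjusted p = 1.8e-11, and adjusted p = 0.49 with an estimated correlation). Among all genes tested 4 members rose, against 21 adjusted over the list alone and 13 among all genes with the block. CTH, which makes cysteine from cystathionine, was 6.17-fold higher, the transcription factor ATF5 5.65-fold, and ASNS, asparagine synthetase, 4.56-fold (6.27 ± 1.32 against 8.45 ± 0.11, SD, n = 4 each, adjusted p = 0.044). With single arrays left out ASNS and ATF5 passed in 1 of 8 cases, without control 2 (adjusted p of ASNS 0.0012 there and up to 0.11 in the others), and CTH in 4. ASNS and ATF5 also did not pass under quantile normalization. DDIT3, another ATF4 target, did not pass (log2 0.91 ± 0.48, SE, n = 4, adjusted p = 0.29, higher in 3 of 4 experiments), except with the block and without experiment 2 (log2 1.42, adjusted p = 0.026, in a range of 0.026 to 0.81), and its change was as small as 0.46, without control 1. Control 2 stood apart here. The mean of the list on it was 1.27 above the mean of the controls, where controls 1, 3 and 4 lay at -1.16, -0.14 and 0.03 and the BCAA-free arrays between 1.28 and 1.69.

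Amino acid transporters shifted the same way (18 tested, median 0.78, adjusted p = 0.00046, and adjusted p = 0.49 with an estimated correlation). Its 4 rises were the cystine transporter SLC7A11, 4.49-fold, its partner chain SLC3A2, 2.78-fold, SLC43A1, a carrier of large neutral amino acids, 2.41-fold, and SLC7A1, a carrier of cationic amino acids chosen after its value was seen (log2 1.08 ± 0.25, SE, n = 4). SLC7A7, also chosen after its value was seen, fell (log2 -0.92 ± 0.22, SE, n = 4). Over the list alone 10 rose and 3 fell, and with the block 6 and 3. Of 22 cytosolic tRNA synthetase genes and cofactors, 2 rose, EEF1E1, a cofactor of the synthetase complex, 2.79-fold (log2 1.48 ± 0.21, SE, n = 4, adjusted p = 0.0094), and the threonyl-tRNA synthetase TARS1, 2.0-fold. Over the list alone 8 rose, and with the block 4. That list was shifted up (median 0.61, adjusted p = 0.0011, and adjusted p = 0.49 with an estimated correlation), although its median in experiment 2 was -0.20 and the experiments of 4 days alone did not give the call (adjusted p = 0.14). With single arrays left out SLC7A11, SLC3A2 and TARS1 passed in 1 of 8 cases, without control 2, SLC7A1 and SLC7A7 in 1, SLC43A1 in 7 and EEF1E1 in all 8. SLC3A2, TARS1 and SLC7A7 also did not pass under quantile normalization. The log2 change of SLC7A11 was 1.42 without experiment 1, and that of SLC3A2 0.87 in the experiments of 4 days alone. On control 2 the means of both lists, 0.40 and 0.36 above the control mean, were the highest among controls.

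Most tested lipid synthesis genes were lower without BCAA, though fewer passed the threshold. In the fatty acid synthesis list 7 of 13 tested members fell and none rose, with 9 falls and 1 rise over the list alone and 8 and 1 with the block (median -1.20, camera adjusted p = 0.00024, and adjusted p = 0.49 with an estimated correlation). Besides FADS2, they included FADS1, a second desaturase, 5.60-fold lower (log2 -2.49 ± 0.43, SE, n = 4), and FASN, fatty acid synthase, 4.34-fold lower (log2 -2.12 ± 0.38, SE, n = 4). In the list of cholesterol synthesis and uptake all 24 tested members had a negative change (median -1.31, adjusted p = 8.4e-10, and adjusted p = 0.49 with an estimated correlation). Among all genes tested 3 members fell, including FDFT1, squalene synthase, 2.80-fold, and over the list alone 18 fell and with the block 10. FADS2 and FADS1 passed without each of the 8 arrays, FASN in 6 cases and FDFT1 in 2. In the experiments of 4 days alone the log2 changes of FASN and FDFT1 were -1.38 and -0.98. The median of the cholesterol list ranged from -0.42 in experiment 2 to -2.69 in experiment 4. On control 2 the cholesterol list mean was -0.97, against 0.07, -0.09 and 0.99 on controls 1, 3 and 4, and the fatty acid list mean was -0.52, against 0.06, -0.0015 and 0.46.

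**Figure D3:**
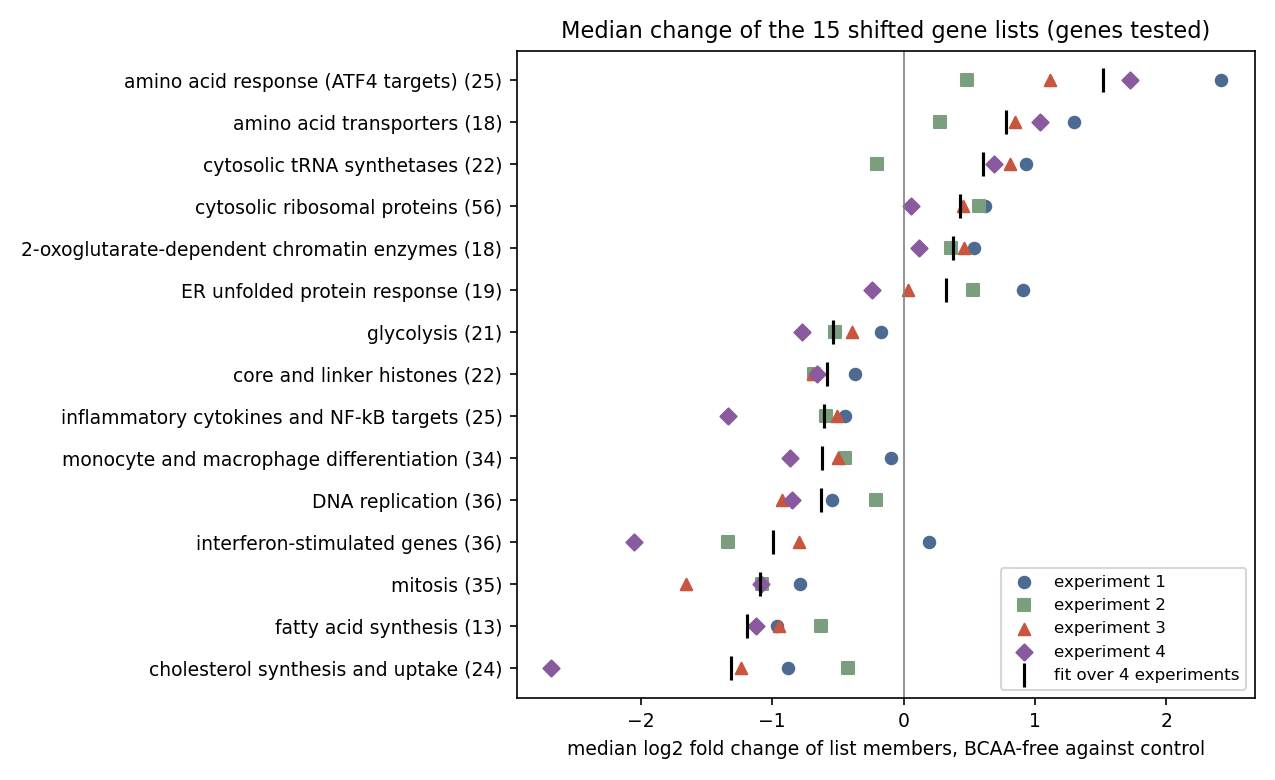
Median log2 fold change of the tested members of the 15 shifted gene lists in each experiment (coloured symbols) and in the fit over 4 experiments (black bar), with the number of genes tested in parentheses. Medians of the fit run from -1.31 for cholesterol synthesis to 1.52 for the amino acid response, while experiment 1 lies above 0 for interferon-stimulated genes (0.20), experiment 2 below 0 for tRNA synthetases (-0.20) and experiment 4 below 0 for the unfolded protein response (-0.24), and the ribosomal protein median of 0.43 is 0.02 under quantile normalization.

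Cell division genes shifted down. Of 35 mitosis genes 23 fell and none rose, with 30 over the list alone (median -1.10, camera adjusted p = 3.5e-19, and adjusted p = 0.49 with an estimated correlation). KIF20A, a kinesin of cytokinesis, was 3.76-fold lower (log2 -1.91 ± 0.29, SE, n = 4, adjusted p = 0.011), the kinase gene AURKB 3.20-fold and the spindle protein gene ASPM 3.16-fold. Of 36 DNA replication genes 7 fell, 16 over the list alone and 12 with the block (median -0.63, adjusted p = 3.1e-09, and adjusted p = 0.49 with an estimated correlation). Examples were RFC3, a clamp loader subunit, 3.22-fold, MCM5, part of the replicative helicase, 2.37-fold, and GINS1, 2.30-fold. Core and linker histone genes also shifted down (22 tested, 5 fell, 8 over the list alone and 8 with the block, median -0.58, adjusted p = 0.00011, and adjusted p = 0.49 with an estimated correlation), with H2AX 2.81-fold, H1-2 2.79-fold and H2AC8 2.19-fold lower. KIF20A and RFC3 passed without each of the 8 arrays, H2AX in 6 cases, AURKB and GINS1 in 5, ASPM and H1-2 in 3, MCM5 in 2 and H2AC8 in 1. The log2 change of AURKB was -1.02 under normexp, and those of GINS1 and H2AX were -0.75 and -0.88 in the experiments of 4 days alone. The mitosis list did not place control 2 apart, at -0.24 against -0.15, 0.16 and 0.23 on the other controls and -0.85 to -1.47 on BCAA-free arrays. The DNA replication list did, at -0.39 against 0.09, 0.24 and 0.05, near BCAA-free 1 at -0.43. Among cell cycle inhibitors and G1 cyclins (17 tested, adjusted p = 0.55) CCND1, cyclin D1, rose 2.40-fold, but did not pass under normexp (log2 0.76) or without 4 of the 8 arrays, each left out singly.

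Some monocyte and inflammatory genes fell, and their lists shifted down at camera's preset correlation. In the monocyte and macrophage list 6 of 34 fell and 7 over the list alone, with 7 falls and 1 rise under the block (median -0.62, camera adjusted p = 0.0028, and adjusted p = 0.49 with an estimated correlation). MPEG1, which encodes a pore-forming protein of macrophages, was 5.32-fold lower (log2 -2.41 ± 0.27, SE, n = 4, adjusted p = 0.0050), and the scavenger receptor CD36 4.15-fold. The proteoglycan gene VCAN fell by less under normexp, where it did not pass (log2 -1.60, and -0.53 there), as did MPEG1, which passed (log2 -1.54), while CD14 did not pass (log2 -0.78 ± 0.34, SE, n = 4, adjusted p = 0.21). Of 25 cytokine and NF-kB target genes 4 fell, 7 over the list alone and 7 with the block (median -0.61, adjusted p = 0.00012, and adjusted p = 0.49 with an estimated correlation), among them the chemokine CCL3, 4.63-fold, IL1B, 3.85-fold, and the interleukin-1 receptor antagonist IL1RN, 3.52-fold. The other was CD83, a surface protein chosen after its value was seen (log2 -1.57 ± 0.38, SE, n = 4). Interferon-stimulated genes shifted down (36 tested, median -0.996, adjusted p = 5.0e-06, and adjusted p = 0.55 with an estimated correlation), with 3 falls, 7 over the list alone and 11 with the block. These were OAS2, 3.65-fold, RIGI, 2.46-fold, for which another probe had the opposite sign, and XAF1, 1.76-fold. The log2 change of RIGI was -0.47 with all its probes averaged, and that of IL1B -1.10 in the experiments of 4 days alone. Without each of the 8 arrays MPEG1, CD36, IL1RN and OAS2 passed throughout, VCAN in 5 cases, RIGI in 3, CCL3 in 2 and IL1B, CD83 and XAF1 in 1. IL1B and CD83 also did not pass under quantile normalization. The list mean of interferon-stimulated genes was not separate between groups, running from -0.77 to 1.23 on controls and from -1.67 to -0.74 on BCAA-free arrays. MHC class II and antigen presentation genes did not shift as a list (19 tested, median -0.03, adjusted p = 0.31, but 0.038 with the block and fry), although 5 fell, with 5 falls and 1 rise over the list alone. They were the activator of these genes, CIITA, above background on 2 BCAA-free arrays, and HLA-DMA, HLA-DMB, HLA-DRA and HLA-DRB1, chosen after their values were seen. The size of the fall of CIITA is uncertain (log2 -1.82, -0.95 with all its probes averaged and -0.28 under normexp). CIITA, HLA-DMB (-0.35) and HLA-DRA (-0.67) did not pass under normexp. HLA-DMB passed in all 8 cases with an array left out, CIITA, HLA-DMA and HLA-DRA in 2 and HLA-DRB1 in 1.

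EZH2, the methyltransferase of polycomb repressive complex PRC2, fell 1.69-fold (5.81 ± 0.06 against 5.05 ± 0.18, SD, n = 4 each, adjusted p = 0.041, lower in all 4 experiments). The call was not kept when any 1 of the 8 arrays was left out (adjusted p 0.052 to 0.10), nor with no filter on dim probes, where more genes were tested, while its log2 change ranged only from -0.84 to -0.65 over all alternatives. SUZ12, its partner, did not pass (log2 -0.26 ± 0.19, SE, n = 4, adjusted p = 0.43, lower in 3 of 4 experiments), nor did the list of PRC2 subunits (11 tested, adjusted p = 0.55) or of PRC1 subunits (19 tested, adjusted p = 0.25). Developmental regulators bound by polycomb in stem cells were not shifted either (18 tested, adjusted p = 0.36). In that list EOMES, a T-box transcription factor, rose 3.08-fold (log2 1.62 ± 0.23, SE, n = 4, adjusted p = 0.0094, and log2 1.01 under normexp). The list of 2-oxoglutarate-dependent chromatin enzymes shifted up (18 tested, median 0.38, camera adjusted p = 0.015, and adjusted p = 0.49 with an estimated correlation). The histone demethylase gene KDM7A was its only rise, 3.56-fold, and 1 rose over the list alone. Without single arrays KDM7A passed in 1 of 8 cases and EOMES in all, and KDM7A did not pass under quantile normalization. The shift of the list was not called with no filter on dim probes (adjusted p = 0.052) or without BCAA-free 2 (adjusted p = 0.056, median 0.22).

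Of the genes that break down BCAA, 2 of 27 fell, both also over the list alone, and the list was not shifted (median -0.15, camera adjusted p = 0.18). BCKDK, the kinase that restrains BCAA oxidation, was 2.36-fold lower (log2 -1.24 ± 0.22, SE, n = 4, adjusted p = 0.017), and AUH, an enzyme of leucine breakdown chosen after its value was seen, had a log2 change of -1.07 ± 0.19 (SE, n = 4). The transaminase genes did not pass, BCAT1 with a log2 fold change of 0.79 ± 0.29 (SE, n = 4, adjusted p = 0.14, 3 of 4 experiments of that sign) and BCAT2 with -0.88 ± 0.31 (SE, n = 4, adjusted p = 0.12, the same sign in 4 of 4). BCAT1 did pass without control 2 (log2 1.09, adjusted p = 0.018) and without experiment 2 (adjusted p = 0.040), but its log2 change was 0.30 in the experiments of 4 days alone, and the adjusted p ranged from 0.018 to 0.81 over all alternatives. With single arrays left out BCKDK passed in 7 of 8 cases and AUH in 6. With normexp background correction the list was past the threshold (median -0.24, adjusted p = 0.0084), and so it was with no filter on dim probes (adjusted p = 0.027), in a range of 0.0084 to 0.55 over its alternatives.

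Glycolysis genes shifted down (21 tested, median -0.54, camera adjusted p = 0.012, and adjusted p = 0.49 with an estimated correlation). The aldolase ALDOC fell 4.43-fold and the glucose transporter SLC2A3, chosen after its value was seen, rose (log2 1.91 ± 0.44, SE, n = 4, and 0.98 under normexp, where it did not pass), with 4 falls and 1 rise both over the list alone and with the block. The call was lost without experiment 4 (median -0.32, adjusted p = 0.053) and in the experiments of 4 days (median -0.30, adjusted p = 0.050). In the ER unfolded protein response list (19 tested, median 0.32, adjusted p = 0.021, and adjusted p = 0.55 with an estimated correlation) the transcription factor XBP1 rose 1.81-fold, and 3 rose both over the list alone and with the block. XBP1 passed in 7 of 24 alternatives, and with single arrays left out it passed in 1 of 8 cases (adjusted p up to 0.11), as SLC2A3 did, and ALDOC in 5. Neither XBP1 nor SLC2A3 passed under quantile normalization. The ER list was called under 14 of 28 alternatives, and not under normexp (adjusted p = 0.15), quantile normalization (0.053), no filter (0.18) or array weights (0.084). It was also lost without experiment 1 (0.35, median 0.08) or 2 (0.085), control 1 (0.21, median 0.11) or 2 (0.053) and BCAA-free 1 (0.065). The tricarboxylic acid cycle list was not shifted (22 tested, median -0.43, adjusted p = 0.069) but was with the block (adjusted p = 0.032), and under 12 of 28 alternatives in all, quantile normalization (0.039) and normexp (0.0046) among them. Left out singly, control 4 (0.045), BCAA-free 1 (0.028), BCAA-free 3 (0.022) or experiment 3 (0.037) also gave that call. All 56 tested cytosolic ribosomal protein genes had a positive change and none passed (median 0.43, adjusted p = 1.2e-11, and adjusted p = 0.49 with an estimated correlation), but under quantile normalization their median was 0.02 (adjusted p = 0.40). Random lists of equally bright genes had a median change of 0.39.

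Markers of other cell types were not shifted, with camera adjusted p-values of 0.095 for T, B and NK cells (15 tested), 0.96 for erythroid cells and megakaryocytes (11 tested) and 0.19 for stromal and epithelial cells (11 tested). Among them CD5, a lymphocyte antigen below background on all BCAA-free arrays, and ACTA2, smooth muscle actin, fell, as did CD3D and PECAM1, chosen after their values were seen. Under normexp CD5 (log2 -0.022), ACTA2 (log2 -0.62, against -1.76) and CD3D (log2 -0.18) did not pass. The bound of at least 1.46-fold for CD5 thus holds only with the processed signals, and ACTA2 passed in 8 of its 23 alternatives. CD5 passed in all 8 cases with an array left out, ACTA2 and PECAM1 in 2 and CD3D in 1. The lymphocyte list passed in the experiments of 4 days alone (adjusted p = 0.048) and with fry (0.024). Other lists without a shift included stem cell and KMT2A-fusion leukaemia genes (adjusted p = 0.25, but 0.032 with the block and fry) and the BCL2 family (0.36), in both of which the survival gene BCL2 rose 1.78-fold. Ribosome biogenesis and MYC targets (0.78) held 1 rise, RRN3, a factor of ribosomal RNA transcription, 1.97-fold, while MYC itself did not pass (log2 0.56 ± 0.29, SE, n = 4, adjusted p = 0.28). The respiratory chain (0.27, but 0.015 under quantile normalization, 0.0046 under normexp and 0.042 with no filter) held a 1.83-fold fall of NDUFS1, p53 targets (0.82) a 2.42-fold fall of DDB2, hypoxia targets (0.96) a 2.24-fold fall of PFKFB4 and immediate early genes (0.79) a 3.33-fold fall of JUN. ANKRD37 and KLF6 also fell in the hypoxia and immediate early lists, and ZMAT3 and ETV5 rose in the p53 and immediate early lists, all 4 chosen after their values were seen. Neither rise passed under normexp (log2 0.56 for ZMAT3 and 0.82 for ETV5). Without single arrays BCL2, NDUFS1, DDB2 and ZMAT3 passed in 1 of 8 cases (adjusted p up to 0.10, 0.10, 0.080 and 0.093), RRN3, PFKFB4 and ETV5 in 2 (up to 0.085, 0.12 and 0.079), ANKRD37 in 5, JUN in 7 and KLF6 in all 8. PFKFB4 also did not pass under quantile normalization. NRF2 targets (0.12, but 0.028 without control 4, 0.014 without experiment 4 and 0.0051 in the experiments of 4 days) held the rise of SLC7A11, and autophagy and lysosome (0.61), myeloblast granule proteins (0.77) and heat shock genes (0.98) held no changed member. In these lists the counts over all genes stayed the same over the list alone, except immediate early genes (2 rises and 2 falls in place of 1 and 2) and p53 targets (3 and 3 in place of 1 and 1). With the block there were 3 rises and 1 fall among stem cell genes, 1 and 5 among immediate early genes, 3 and 2 among p53 targets, 2 rises among developmental regulators, 2 falls among autophagy genes, and 1 rise each among PRC1 subunits, granule proteins, erythroid markers and hypoxia targets. The median and the test had opposite signs for the BCL2 family, p53 targets, heat shock genes, ribosome biogenesis and hypoxia targets.

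In sum 15 of the 36 lists shifted, 6 up and 9 down, and 16 did so with the block. None was called with an estimated correlation, and 6 were past fry, namely mitosis, DNA replication, fatty acid synthesis, amino acid transporters, the monocyte list and the lymphocyte markers. With the block 8 were past fry, namely mitosis, histones, fatty acid synthesis, the tricarboxylic acid cycle, lymphocyte markers, BCAA catabolism, stem cell genes and MHC class II. Of all tested genes 4.92% changed. The lists of 2-oxoglutarate-dependent chromatin enzymes (1 of 18) and of the ER unfolded protein response (1 of 19) lay near that share. In each the changed member was a rise. Of all 15759 tested genes 260 rose, a lower share, and 1 member is too few to set against it. Glycolysis held 1 rise and 1 fall among 21 genes, and none of 56 ribosomal protein genes changed. Camera at the preset correlation also called a median of 10 lists when the 8 arrays were split in other ways, with 14 at the highest. Some of those splits keep most arrays of a group together and so still hold part of the difference between the groups.

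The 4 experiments differed in length, which allows a test of whether the response changed with culture time. No gene's response had a slope on the number of days past the threshold in limma, the lowest adjusted p was 0.998, and 562 genes had an unadjusted p under 0.05. With 1 experiment each of 3 and 5 days, the slope also holds any other difference between those experiments. It rests on 4 ratios per gene, so the test had little power. The absence of calls does not show that the response was the same at all times. The median change of cholesterol genes was -2.69 at 3 days, -0.88 and -0.42 in the experiments of 4 days and -1.24 at 5 days. That of mitosis genes was -1.09, -0.79, -1.08 and -1.66 in the same order, and that of amino acid response genes 1.72, 2.42, 0.49 and 1.11.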

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

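The tests of a mixture, a swap and a dim array for control 2, of quantile normalization for the excess of falls, and of the size of the change in equally bright genes were chosen after the result was seen. The percentile of the ribosomal protein list among equally bright lists and the other splits of the arrays were set before theirs.

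Among the 4 arrays of a group, 1 lay far from the rest for 7 of 138 gene-by-group sets of named genes (5.07%), for 2 of 18 array summaries and for none of 72 list means, and chance marks about 1 in 20. PRSS8 stood at -0.31 on control 2 against -2.26 to -1.98 on the other controls, and TARS1 at 7.14 on control 2 against 6.23 to 6.26. OAS2 stood at 2.05 on control 4 against 1.33 to 1.42. On BCAA-free arrays NNMT stood at 1.51 on array 1 against -1.19 to -0.80, PRL at -4.19 on array 1 against -6.78 to -6.45, H2AC8 at 0.88 on array 3 against 1.53 to 1.61, and CCL3 at 2.0 on array 4 against 2.70 to 2.81. Control 4 had 263 spots marked as outliers against 143 to 152 on the other controls, and the median local background was 21 on BCAA-free 4 against 22 on the other BCAA-free arrays. Outside the named genes, 242 of 9411 probes that matched no gene symbol changed, 84 up and 158 down. That is 2.57%, against 4.92% of all tested genes with a symbol, and with the block 649 changed.

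Control 2 lay near the BCAA-free arrays for amino acid response genes, with a list mean of 1.27 against -1.16 to 0.03 on the other controls. A mixture with BCAA-free RNA as the whole cause would imply 1 share for every list. Mitosis genes implied 38.7% (95% bootstrap interval over 25 genes 24.2 to 48.8) and lipid synthesis genes 83.2% (30 genes, 77.9 to 89.2). Their difference was -44.5 points (-60.2 to -34.2). Amino acid response genes, at 74.6% (18 genes, 69.7 to 87.6), lay near the lipid share. The intervals take genes as independent and leave out the spread between the other controls, so they are likely too narrow. The DNA replication list, for which no share was computed, had a mean of -0.39 on control 2. It lay near BCAA-free 1 (-0.43), against 0.05 to 0.24 on the other controls. The shares of mitosis and lipid genes differed, but a mixture is not excluded. A swap with BCAA-free 2 would put that array out of place, and its list mean of 1.61 lay within the 1.28 to 1.69 of the other 3. The dimmer control 4 had a list mean of 0.026, which argues against brightness. A different state of that culture, such as its nutrient supply, stays open and was not tested.

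Ribosomal protein genes were higher without BCAA under percentile scaling but not under quantile normalization, and their median per experiment was 0.62, 0.57, 0.46 and 0.05 where the control array was 2.49, 1.81, 1.49 and 1.03 times as bright as its partner. Among 10000 random lists of equally bright genes the median change was 0.39 (central 95% 0.35 to 0.42) against 0.43 for the list. Most of the shift may therefore come from how brightness differs between the arrays, which moves bright genes in general. By the rule set beforehand, a median above the central 95% of those lists counts against brightness. The list's median lay at their 98.5th percentile, so that rule was met. But those lists take genes as independent, while the list's genes had an estimated correlation of 0.61. Under quantile normalization the median was 0.02, a condition that was not part of that rule. An excess beyond brightness therefore cannot be read. No biological explanation was tested.

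More genes fell than rose. Unequal distributions of signal between the brighter control arrays and the others, as the whole cause, would bring the share of falls close to that of rises once quantile normalization made the distributions equal. That step moved ribosomal protein genes, but 68.3% of changed genes still fell (58.9% to 80.7% with each of the 8 arrays left out), against 66.5% without it, which argues against that cause. Loss of dim signals on dimmer arrays is not removed by it and stays open, with 61.3% falls among genes above background on all 8 arrays and 75.5% with no filter. The absence of BCAA and the slide row cannot be told apart, because each group filled 1 row, and no test of the row was possible.

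Of the 35 splits of the 8 arrays into 4 and 4, the real one alone gave as many as 776 genes, or 636 at least 2-fold, and the highest of the others was 0 in both cases. The samples are paired, so the 35 splits are not equally likely under chance. Splits that mix the groups also place the difference between groups in the spread, which lowers their counts. Chance can therefore not be excluded from the 35 splits. Among the 8 splits that part all 4 pairs, as the real one does, no other gave any gene either, but 8 are too few for a share under 0.05. For the gene lists the real split was also the only 1 of 35 to give 15, but the highest other gave 14, also among the 8 that part all 4 pairs. The split with 14 that parts all pairs set control 1, 2 and 4 with BCAA-free 3, and so still held part of the difference between the groups. A split of control 1 and 2 with BCAA-free 2 and 4, which balances the groups, gave 14 too. The number of lists is thus little evidence in itself. Members of a list that passed can be set against the 4.92% of all tested genes that changed. Genes of a list move together, however. Estimated correlations in the shifted lists ran from 0.045 for the monocyte list to 0.73 for cholesterol genes. The counts of passed members were not tested and only describe a list.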

How the results depend on the processing

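The settings that combine the block with the loss of experiment 2, an estimated correlation or fry were chosen after seeing the data. The counts of 776 changed genes and 636 changed at least 2-fold fell to 229 and 228 with no filter on dim probes, where more genes were tested, and to 0 and 0 with the experiments of 4 days alone, where fewer arrays were. With the experiment as a block they were 1661 and 1079, and with the block but without experiment 2 they were 1413 and 1231. Leaving out 1 array or 1 experiment moved them over 24 to 1229 and 24 to 1020. Without control 2, the array nearest the other group, 1229 genes changed, while leaving out any other array gave 474 or fewer, and without experiment 3 or 4 there were 55 and 24, the cause of which was not tested. The 15 shifted lists ranged over 14 to 17 in these settings, and were 0 with an estimated correlation, 6 with fry, 0 with the block and an estimated correlation and 8 with the block and fry. Under all other alternatives the counts stayed within 1.5 times, with 607 to 1138 genes. Normexp was the lowest of these, and there 44 of the 776 genes had the opposite sign, among them CD274 (log2 0.20). How many of these signs came from the offset alone was not tested. Between 61.3% and 73.3% of changed genes fell in them, against 66.5%. No gene passed for culture time with no filter (1077 at an unadjusted p under 0.05) or quantile normalization (528). The fit with the slide or scan as a block was not run, since all arrays share 1 slide.

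No gene named by the rule and no list reversed. Over alternatives other than leaving out an array or experiment, named genes kept their side of the threshold in 682 of 819 cases, lost it in 135 and gained it in 2, and with arrays or experiments left out they kept it in 444 of 828. The blocked fit changed no call of a named gene, and among lists added the tricarboxylic acid cycle. MPEG1, ANXA2 and PRSS8 passed under 23 of 24 alternatives, whereas EZH2 passed under 9 of 24 (adjusted p 0.021 to 0.47), ASNS under 11 and IL1B under 8. Dim probes limit what can be read: normexp with its offset reduced the log2 change of PRL from -4.17 to -0.97 (adjusted p = 0.053, in a range of 0.0016 to 0.34).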

Other observations

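The groups of genes below were formed after the data were seen, from symbols that share a stem, and the test of EZH2 was chosen after its result was seen. Of 270 stems with at least 8 tested genes, 9 were past the camera threshold, and each had an adjusted p of 0.96 with an estimated correlation. Under quantile normalization the ribosomal stems RPL and RPS (adjusted p 0.58 and 0.57) and the chemokine stem CCL (0.074) were not past it, and the other 6 were. Annexin symbols were lower without BCAA (15 tested, median -0.97, adjusted p = 3.2e-05), with 7 falls. Beside ANXA2 and its pseudogenes these were ANXA8L1, 6.64-fold, ANXA1, 6.24-fold, ANXA5, 1.96-fold, and ANXA2R, 2.15-fold, which encodes a receptor and not an annexin. Of 63 symbols made of CD and a number 10 fell and 1 rose (median -0.55). The tetraspanin CD53 was 7.23-fold lower, while CD38, an enzyme that consumes NAD, rose 2.77-fold. CD84, above background on only 2 BCAA-free arrays, fell by an uncertain amount (log2 -2.86, and -0.85 under normexp). The immune checkpoint ligand CD274, below background on all BCAA-free arrays, passed as a fall (log2 -1.23). Under normexp it had the opposite sign (log2 0.20, adjusted p = 0.65), which the offset favours for so dim a probe. No direction can be read from these values. Without single arrays in turn ANXA1, ANXA8L1, CD53 and CD84 passed in all 8 cases, ANXA2R and CD38 in 3, ANXA5 in 2 and CD274 in 1. Kinesins (32 tested, median -0.45) held 8 falls, which overlap the mitosis list.

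Small nucleolar RNA symbols of the SNORD stem had a small positive median (0.20, with 0.22 under quantile normalization). It was 0.09 and 0.05 in experiments 2 and 4. Of 125 tested 7 rose and 0 fell, where 260 of all 15759 tested genes rose and 516 fell. Among the 7 rises SNORD116-26, SNORD116-27, SNORD116-29 and SNORD108 come from a single imprinted host transcript, and SNORD116-27 was 3.37-fold higher (log2 1.75 ± 0.27, SE, n = 4). Under normexp its log2 change was 0.97, and SNORD116-26 and SNORD116-29 did not pass (log2 0.94 and 0.80). SNORD116-27 passed in all 8 cases with an array left out, SNORD108 in 4, SNORD116-26 in 2 and SNORD116-29 in 1. Golgin symbols of the GOLGA stem had a median of 0.49 over 25 tested genes, with 1 rise, GOLGA6A, 2.67-fold, which passed in 4 of 8 such cases. Many of these are near-identical copies that probes cannot separate.

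EZH2 may have fallen because fewer cells were dividing. Its log2 change of -0.75 lay within the 10th to 90th percentiles of the changes of DNA replication genes, -1.15 to -0.23. That span is wide enough to hold most modest falls, so lying in it cannot tell this hypothesis from others. The order over experiments 1 to 4 differed, with -0.72, -0.68, -1.08 and -0.53 for EZH2 and medians of -0.54, -0.21, -0.92 and -0.85 for DNA replication genes. A specific effect of BCAA on EZH2 stays open and was not tested.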
